A study of Mus musculus with 6 samples.

How the data were processed

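CUT&Tag for H3K4me3, H3K27me3 and normal rabbit IgG was made from cultured neural stem and progenitor cells of the mouse forebrain at E13.5, after 24 h with water or 10 mM crotonate, per the labels. This gives 6 samples, with 1 library per antibody and treatment. Peak lists of the 4 libraries of the marks were used, and the 2 IgG samples were not analysed here.

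The deposited lists give 1 line per peak with 1-based start and end, length, summit and 4 measured values, in the column layout of MACS2, per the file headers. Pileup at the summit is a signal, scaled by 1 factor per library by the authors' caller, as deposited. Significance is given as −log10 of p and of q against the caller's local background, per the file headers. Fold enrichment is a linear ratio formed from summit signal and that background by the authors' caller before deposit, per the file headers. It was read here as a ratio with 1 added to both signal and background, which the headers do not state. On that reading, the fold enrichments quoted and the threshold of 5 are smaller than plain ratios of signal to background. Every deposited peak had q under 0.05. Bowtie2 2.4.1, SAMtools 1.10, Picard 2.22.0 and MACS2 2.2.7.1 and the build GRCm38 are named, per the submitters' processing notes. Their settings, the handling of duplicates and the library used as background are not given in the sources used here. The peak values are the authors' own and were mainly used to describe, rank or filter peaks within 1 list. Exceptions were the alternatives that apply 1 threshold to both lists of a mark, the estimates of depth and the comparison of local background between treatments. Peak calling per library makes list length and peak width depend on depth, and a peak absent from a list can lie just under the threshold there.

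Fragment totals are not given, so relative depth was read from the lists. All pileups of a list were whole multiples of 1 step (100% within 0.006), which is the scaling factor of that library, and the lowest local background gave a floor. From each peak's own pileup and the local background implied by its fold enrichment, −log10 p was also recomputed. It came to within 1% of the deposited value for about 99.5% or more of the peaks of each list. This checks how p was formed and not the estimates of depth, since neither step nor floor enters it. The floors of both marks of a treatment, per bp, lay close together, which is how 1 background library for both would look, but the sources used here do not name it. The floor per bp was the floor divided by the length of the shortest peak of the list. Its ratio gave a background 1.80 times as deep after crotonate as after water. With the steps, the marked libraries came to 1.16 times (H3K4me3) and 0.810 times (H3K27me3). These estimates assume that the shortest peak has the fragment length and that each library was scaled to its background, which was not tested.

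Peaks were compared with code written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak was shared when it overlapped a peak of the other list of the same mark by at least 1 bp, and bedtools 2.31.1 gave the same numbers of shared peaks. Shares have exact Clopper-Pearson 95% intervals for counting error only, and the share expected by chance came from 100 placements of the same peaks at random positions of the same chromosomes.

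Genes came from a RefSeq gene table of GRCm38.p6, the same build as the peaks, which holds gene spans and no strand or transcript. The planned promoter, 2 kb either side of an annotated transcription start, was therefore replaced by 2 kb either side of both annotated ends of each of 21887 protein-coding genes on chromosomes 1 to 19, X and Y. This adds 3′ ends, misses starts inside a gene and can assign a peak to a neighbour. A gene was marked when a peak overlapped such a window by at least 1 bp. The state "both" needed both marks at the same end, and genes with the marks at different ends were kept apart. A mark was gained when it was called after crotonate only and lost when called after water only. A gain was called new when no peak behind it overlapped a peak of the other list. That definition was revised after named genes had been looked at.

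The comparisons, 14 gene lists with 402 genes in all, the rule for named genes and 10 of the alternatives were chosen before the data were examined. The rule named, per mark, the 10 genes that gained and the 10 that lost it with the highest −log10 q, the 10 genes with both marks that lost H3K27me3 with the highest −log10 q of that peak, and up to 4 members per list that gained and 4 that lost a mark. It also named Sox2, Nes, Pax6, Neurog2, Gfap, Actb and Gapdh in every case. Some items that the rule names are not reported here. Other members of lists with few gains, the strongest genes with a peak in 1 list only, and the bivalent examples were chosen after their values were seen. The lists covered neural stem, neuronal, ventral forebrain, glial, Hox, non-neural factor, cell cycle, signalling, crotonylation, Polycomb and housekeeping genes and markers of microglia, endothelium and mural cells. The number of members that gained or lost a mark was set against 10000 random lists of protein-coding genes matched on state in water. This describes the libraries and does not test the treatment.

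The alternatives planned were a threshold at the median −log10 q of the shorter list of each mark (37.7 for H3K4me3 and 4.75 for H3K27me3), a fold enrichment of at least 5, lists of equal length by −log10 q, a reciprocal overlap of 50%, sharing within 1 kb, merging within 1 kb, windows of 1 and 5 kb, 200 bp of a window covered, and chromosomes 1 to 19 and X. Added after seeing the data were a matched background depth, genes with no end of another protein-coding gene within 4 kb, the end carrying H3K4me3, and whole genes with 2 kb either side. At the matched depth, p of the crotonate peaks was recomputed with pileup and background scaled to the water background, and peaks at or above the lowest −log10 p of the water list were kept, 15041 for H3K4me3 and 11256 for H3K27me3. This reaches only peaks already called and leaves their starts and ends as they were, so peak widths and gains through a wider peak were not matched for depth. The number of lost H3K27me3 peaks on H3K4me3 was set against that of other peaks in the same of 5 groups by −log10 q and of 5 groups by length, also after the data were seen.

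The steps were tested on simulated data. Of 7643 water H3K27me3 peaks, 1000 removed from a copy of the list were all reported as absent, with 0 wrong. Of the 21887 genes, 400 of 400 with a peak placed at an end were called marked, and 500 of 500 compared with a plain search were called alike. Simulated depth steps were recovered with an error of at most 0.000197%. Of 1000 random gene lists, 26 reached 5% or less of draws.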

Results

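Neural stem and progenitor cells isolated from the forebrain of E13.5 mouse embryos and grown in culture were kept for 24 h with water or with 10 mM crotonate, the salt of a short-chain fatty acid that cells convert to crotonyl-CoA, the donor for histone crotonylation. Chromatin was profiled by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA beside a histone mark. The marks were H3K4me3, found at active and poised promoters, and H3K27me3, the mark placed by Polycomb repressive complexes over silent developmental genes. Peak lists from 4 of the 6 samples were compared, 1 per mark and treatment, and the 2 IgG samples were not analysed here. With 1 library per mark and treatment there was no replicate, so the differences have no replicate check and no p-value is given. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. The lists do not state fragment totals, so depth was estimated from the steps of the pileup values and the background floors. This gave 1.16 times as many H3K4me3 fragments after crotonate as after water and 0.810 times as many H3K27me3 fragments. The background used in peak calling was an estimated 1.80 times as deep after crotonate, so lists of the same mark differ in the power to call a peak.

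The first comparison asked how crotonate changed H3K4me3. Sox2, the gene of a transcription factor that maintains neural progenitors, carried H3K4me3 at its ends in both conditions, with a peak of 3.98 kb after water and 11.6 kb after crotonate. Nes, which encodes the intermediate filament nestin, had peaks of 4.70 and 5.00 kb. The housekeeping genes Actb and Gapdh carried H3K4me3 in both lists too, over 3.36 and 3.66 kb after water and 4.42 and 4.16 kb after crotonate. At Pax6, a regulator of cortical progenitors on chromosome 2, no peak lay at the annotated ends, and an H3K4me3 peak inside the gene spanned 105674962 to 105678204 after water and 105673776 to 105678255 after crotonate. Gfap, the astrocyte intermediate filament gene, had no peak of either mark at its annotated ends. In all, 13221 H3K4me3 peaks covering 21.4 Mb were called after water and 16007 covering 29.4 Mb after crotonate. Of the water peaks, 99.3% (99.1 to 99.4, 13129 of 13221) overlapped a crotonate peak, against 2.23% at random positions, and 92 did not. Of the crotonate peaks, 3371 had no counterpart in water. Those were short, with a median of 469 bp, and made up 6.61% of the covered length. With lists of equal length, 898 crotonate peaks and 398 water peaks had no counterpart. Among 12093 peaks that paired 1 to 1 between the lists, 94.5% were wider after crotonate, with medians of 1536 and 1968 bp. Peak width depends on depth, which differed between the lists, and no alternative matched it for width.

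**Figure D1:**
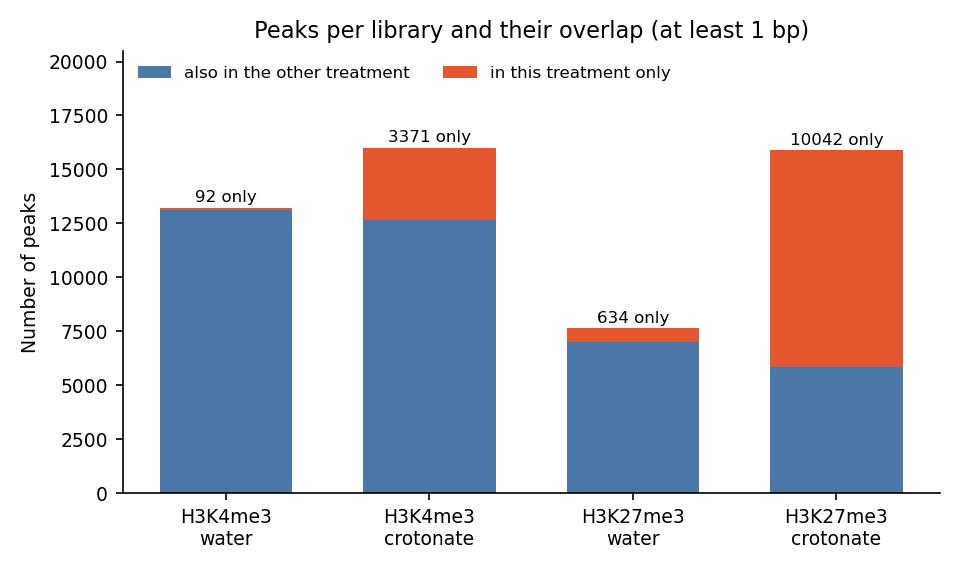
Number of peaks (vertical axis) in each list of H3K4me3 and H3K27me3 after water and after crotonate (horizontal axis), with each bar split into peaks that overlap the other list of the same mark by at least 1 bp and peaks in that list only. Crotonate lists were longer for both marks, with 3371 H3K4me3 and 10042 H3K27me3 peaks in the crotonate list only.

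Gains and losses were then assigned to genes. A gene was taken as marked where a peak reached within 2 kb of either of its annotated ends, since the reference used here gives no strand. By this measure 915 protein-coding genes gained H3K4me3 after crotonate and 11 lost it, out of 21887. The gains with the strongest peaks were at Cpt1b, Gm12657, Nxnl1, Mpig6b, Mamdc4, Tssk1, 6030468B19Rik, Tcf25, Cdkn1a and Ankrd44, and in 10 of these 10 the peak was also in the water list but did not reach the 2 kb window there. Cdkn1a encodes the cyclin-dependent kinase inhibitor p21 and lies on chromosome 17 from 29090979 to 29100722. Its peak spanned 29093415 to 29095821 after water, inside the gene, and 29090699 to 29096507 after crotonate. Of the 915 gains, 74 were of this kind, and 841 (91.9%) rested on peaks with no counterpart in water. Among the latter, by a rule added after the data were seen, the strongest were at E130311K13Rik, Plcg2, Radil, Dera, Lcp1 and Lrrc63 (which shared a peak), Emc9, Dab1, Dgkk and H2-T-ps. Plcg2 encodes a phospholipase C of immune cell signalling, and its peak was 0.996 kb long with an authors' fold enrichment of 19.8. Dab1, the adaptor of reelin signalling in migrating neurons, had a peak of 2.31 kb with a fold enrichment of 15.9. The 10 strongest losses, whether or not the peak was in 1 list only, were at Lin28a, Drc7, Zfp93, Rragb, Tef, Mef2b, Gstm7, 4932438H23Rik, Ggnbp1 and Gpr62. Lin28a, which encodes an RNA-binding protein that blocks let-7 maturation, lies on chromosome 4 from 134003330 to 134019196 and had the strongest lost peak, 1.32 kb long with a fold enrichment of 33.5, but that peak and those of 3 others of the 10 were present in the crotonate list outside the window. The count of gains was 502 with lists of equal length. It rose to 3111 when only peaks at or above the median −log10 q of the water list were used in both lists. Median −log10 q was 37.7 after water and 57.5 after crotonate. The threshold also drops water peaks, so most of the 3111 genes still had a weaker H3K4me3 peak called in water.

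The second comparison asked how crotonate changed H3K27me3. The long Polycomb domains were in place under both conditions. The Hoxa cluster on chromosome 6, from 52155367 to 52260880, and the Hoxc cluster on chromosome 15, from 102921131 to 103036856, were covered over 100% of their length in both lists. Coverage of Hoxd was 99.3% after water and 100% after crotonate, and that of Hoxb was 75.9% and 79.7%. Domains of at least 10 kb numbered 398 after water and 537 after crotonate. At Neurog2, a proneural gene on chromosome 3 from 127632733 to 127635636, the domain measured 24.3 and 23.9 kb. The lists held 7643 peaks over 20.7 Mb after water and 15879 over 33.0 Mb after crotonate. Of the water peaks, 91.7% (91.1 to 92.3, 7009 of 7643) overlapped a crotonate peak, against 2.39% at random positions, and 634 did not. The 10042 peaks in the crotonate list only were short and weak, with a median of 600 bp and a median −log10 q of 3.21, and 0 of them reached 10 kb. They made up 23.7% of the covered length, and 12.9% lay at a gene end, compared with 35.3% of the shared crotonate peaks. At a matched background depth, an alternative chosen after the data were seen, 5860 peaks in crotonate only were left. With a required reciprocal overlap of 50%, the share of water peaks found again fell to 43.9%.

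At genes, 698 gained H3K27me3 and 84 lost it. The strongest gains, at Aup1, Arhgef1, Actr5, Asb10, Pih1d1, Ruvbl2, Uts2r, Foxs1, Lpin3 and Zfp648, were edges of domains found in both lists: the domain counted for Aup1 was that of Pcgf1, a Polycomb subunit gene, which measured 18.6 kb after water and 20.1 kb after crotonate. Of the 698 gains, 640 rested on peaks in the crotonate list only. By the rule added after the data were seen, the strongest of these were at Ptgdr, Ifna1, Asphd1 and Sez6l2 (which shared a peak), Dusp9, Fam222a, Trpc6, Scgb3a2, Perp and Th. Ptgdr, which encodes a prostaglandin D2 receptor, had a peak of 1.58 kb with a fold enrichment of 12.6, and Th, which encodes the rate-limiting enzyme of dopamine synthesis, had one of 6.44 kb with 7.54. The strongest losses were at Cyp26b1, Psmd14, Bin2, Ndnf, Ntng2, Trim47, Socs2, Prob1, Spata24 and Stx3, and 5 of these 10 rested on a peak absent from the crotonate list. At Cyp26b1, whose product degrades retinoic acid, the domain stayed but moved: it spanned 84580283 to 84592113 on chromosome 6 after water and 84578010 to 84590480 after crotonate, which took its edge out of the window. Gains of H3K27me3 numbered 311 and losses 201 with lists of equal length, and 471 and 139 at a matched background depth.

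The third comparison concerned genes carrying both marks, called bivalent, a state associated with developmental genes held poised in stem cells. After crotonate more genes carried both marks at the same end, 1491 against 842 after water. With lists of equal length 1021 genes carried both marks after crotonate, and at a matched background depth 1298 did, against 842 in water each time. Neurog2 and Eomes, neurogenic transcription factor genes, and Dlx1, Dlx2 and Shh, ventral patterning genes, carried both in both conditions. Genes with H3K27me3 only in water were the main source: 406 of 1110 (36.6%) came to carry both, among them Dlx5, Dlx6, Neurod1, Fezf2 and Gad2. A further 209 genes came from H3K4me3 only, 60 from neither mark and 40 from genes whose marks lay at different ends. Of the 842 genes with both marks in water, 776 (92.2%, 90.1 to 93.9) kept both and 63 (7.48%, 5.80 to 9.47) kept H3K4me3 and lost H3K27me3. Losing H3K4me3 was seen at 0 of 842 genes, which allows a share of up to 0.437%. Counted as peaks, 910 H3K4me3 peaks lay on H3K27me3 after water (6.88%, 6.46 to 7.33) and 1717 after crotonate (10.7%, 10.3 to 11.2), against 1.21% and 2.23% at random positions. The share that lost H3K27me3 was 12.1% at a matched background depth, 15.6% with lists of equal length and 17.6% above the median −log10 q, where 74 genes carried both marks in water and 364 after crotonate.

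Among the genes that kept H3K4me3 and lost H3K27me3, the 10 with the strongest water peak were Ndnf, Socs2, Stx3, Tesc, Inhbb, Mycn, Kcnn3, Dlgap4, Kif5c and Mdga1. Mycn, a Myc family transcription factor gene that drives progenitor proliferation, lies on chromosome 12 from 12936093 to 12941836. It had an H3K27me3 peak of 2.05 kb and an H3K4me3 peak of 4.27 kb after water, and an H3K4me3 peak of 4.79 kb alone after crotonate. Ndnf, encoding a secreted neurotrophic factor, lies on chromosome 6 from 65671611 to 65712323. It carried H3K27me3 over 2.24 kb with a fold enrichment of 11.3, the strongest of the 10, beside H3K4me3 of 1812 bp after water and 2217 bp after crotonate. Socs2, a suppressor of cytokine signalling, and Tesc, encoding a calcium-binding protein, had lost H3K27me3 peaks of 0.989 and 3.30 kb. Inhbb encodes the activin beta B subunit, and Kcnn3 a calcium-activated potassium channel. Kif5c and Dlgap4 encode a neuronal kinesin and a postsynaptic scaffold protein. Of the fixed lists, neuronal differentiation genes lost H3K27me3 at 0 of 16, neural stem and progenitor genes at 0 of 4 and signalling genes at 0 of 32, and Mycn was the only gene of the 14 lists to lose it. A loss here means that no H3K27me3 peak was left at either end. Rbfox3 of the neuronal list went from both marks at the same end to marks at different ends. Its strongest H3K27me3 peak measured 4.27 kb (−log10 q 27.3) in water and 0.625 kb (2.51) after crotonate. At the end with H3K4me3 alone, 2 list genes lost H3K27me3. Over the 63 genes the lost peaks had a median −log10 q of 2.82, at percentile 28.4 of the water list, against 15.6 at the 779 genes where the mark stayed.

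The share of genes that gained H3K4me3 differed with their state in water. The states were not matched on kind of gene: 1103 of the 8946 genes with neither mark were olfactory receptor genes. Genes with H3K27me3 only gained H3K4me3 in 418 of 1110 cases (37.7%, 34.8 to 40.6), and genes with neither mark in 497 of 8946 (5.56%, 5.09 to 6.05). Of the 418, 407 rested on peaks with no counterpart in water. The strongest of these, named by the rule added after the data were seen, were at Plcg2, Lcp1, Lrrc63, Dab1, Irf4, Lingo1, Ly6h, Gdf7, Cdk5r2, Crhr1, Nfe2l3, Ifnlr1, Slc6a3, Rasal1 and Kcnh3. Lingo1 encodes a neuronal inhibitor of myelination, Cdk5r2 an activator of the neuronal kinase Cdk5 and Slc6a3 the dopamine transporter. At Kcnh3, a voltage-gated potassium channel gene, a new H3K4me3 peak of 2.63 kb lay in an H3K27me3 domain of 10.9 kb in water and 11.7 kb after crotonate. The gained peaks at H3K27me3-only genes were weak, with a median −log10 q of 8.06 against 57.5 over the whole crotonate list. With peaks at or above the median −log10 q of the water list alone the contrast turned, to 17.9% of H3K27me3-only genes and 21.7% of genes with neither mark. That threshold also removes water peaks, so states in water were called anew and these are not the same sets of genes as above. With lists of equal length the shares were 20.4% and 3.09%. H3K27me3 was gained by 266 of 10872 genes with H3K4me3 only (2.45%, 2.16 to 2.75) and 432 of 8946 with neither mark (4.83%, 4.39 to 5.29). At a matched background depth 158 of the 266 gains and 313 of the 432 were kept.

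**Figure D2:**
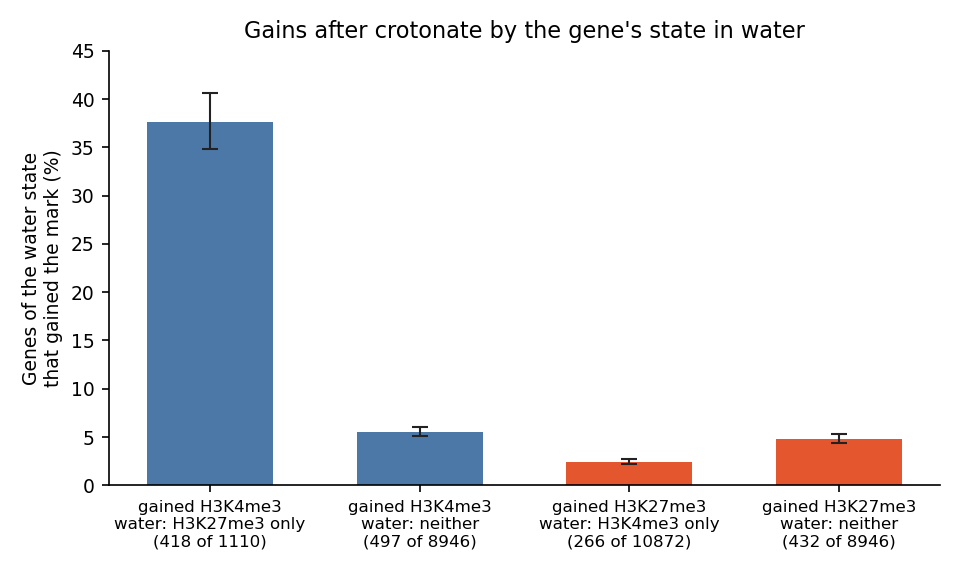
Percent of genes (vertical axis) that gained H3K4me3 (blue) or H3K27me3 (red) after crotonate, by their state in water (horizontal axis); bars are shares of genes and error bars exact 95% binomial intervals that cover counting error only. H3K4me3 was gained by 37.7% of genes with H3K27me3 only and by 5.56% of genes with neither mark.

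Gene lists fixed beforehand were compared with random genes in the same state in water. The ventral forebrain and interneuron list had 7 gains of H3K4me3 among the 13 members that lacked it, at Dlx5, Dlx6, Gad2, Lhx6, Lhx8, Gsx2 and Npy, and the members carrying both marks rose in number from 6 to 13 of 20. Dlx5 and Dlx6, homeobox genes of GABAergic neuron development, lie on chromosome 6 at 6877801 to 6882068 and 6863334 to 6867970. New H3K4me3 peaks lay at 6881431 to 6882111 by Dlx5 and at 6862671 to 6863036 and 6863303 to 6864244 by Dlx6, within an H3K27me3 domain of 45.8 kb in water and 46.3 kb after crotonate. Gad2, which encodes a GABA-synthesising enzyme, had a new peak of 1.15 kb with a fold enrichment of 9.37, and Lhx6, a factor of interneuron migration, one of 1.02 kb with 6.53. The count of 7 stood against a mean of 4.57 over 10000 random lists, 12.4% of which had as many. In the neuronal differentiation list 4 of 13 gained H3K4me3, at the proneural genes Neurog1, Neurod1 and Neurod2 and at Fezf2, a factor of deep-layer cortical neurons, against a random mean of 3.93 (59.6% had as many). The new peaks at Fezf2 and Neurod1 measured 1.04 and 0.807 kb, with fold enrichments of 12.7 and 10.1. Of the signalling list, 6 of 15 gained it, namely Wnt1, Wnt10a, Axin2, Grem1, Msx2 and Gdf7, against 5.32, though Axin2 already had an H3K4me3 peak of 4.05 kb inside the gene in water. All of these counts lay within the central 95% of random lists, which ran from 2 to 8, from 1 to 7 and from 2 to 9.

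**Figure D3:**
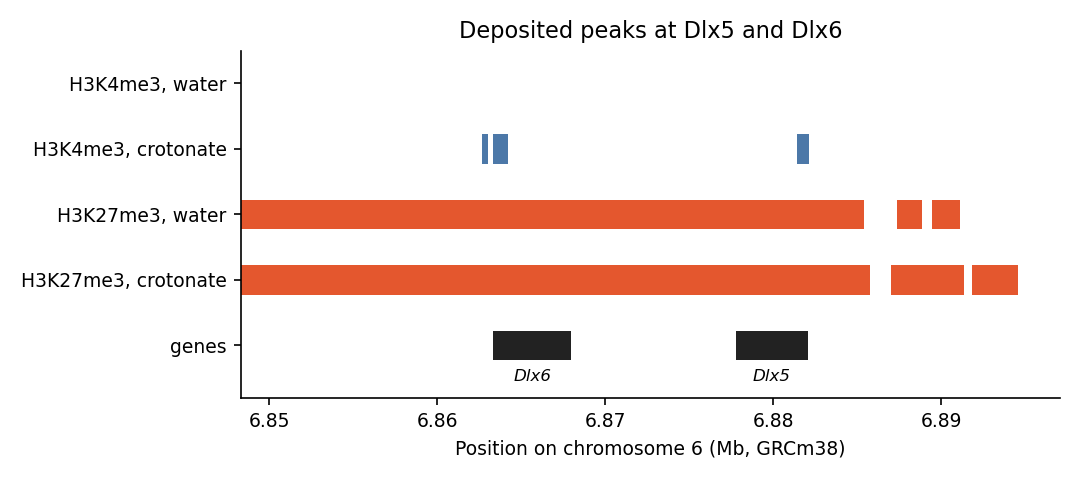
Map of the Dlx5 and Dlx6 locus on chromosome 6 (horizontal axis, position in Mb in GRCm38), with the genes and the deposited peaks of each library drawn as boxes on lines of their own; the long domain runs on beyond the left edge. The H3K27me3 domain of 45.8 kb in water and 46.3 kb after crotonate covers both genes, and the 3 H3K4me3 peaks by the gene ends are in the crotonate list only.

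Hox genes and transcription factor genes of non-neural lineages gained H3K4me3 less often than random genes of the same state. All 39 Hox genes of the list carried H3K27me3 only in water, and 1 gained H3K4me3, against a random mean of 14.7, and none of 10000 random lists was as low. The Hox genes lie in 4 clusters and are not independent of each other. Of the non-neural factors, 4 of 44 gained H3K4me3, at Gata6, Pax2, Tbx1 and Spi1, against a mean of 13.3, with 0.01% of random lists as low. Gata6, an endoderm and heart factor gene, had a new peak of 1.41 kb with a fold enrichment of 8.36, and Pax2, a kidney and eye factor gene, one of 0.553 kb with 4.49. Tbx5 and Meox1, factors of heart and mesoderm, gained H3K27me3, with peaks of 3.39 and 3.63 kb, among the 10 members without it in water (random mean 0.474, 8.07% had as many).

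Of the cell cycle list, 3 of 3 genes without H3K4me3 at their ends in water were counted as gains, Cdkn1a, Cdkn1c and Ccnd3, against a random mean of 0.500, and 0.13% of random lists had as many. Without Cdkn1a, which was marked inside the gene in water, and with new peaks only, a count chosen after the data were seen, it was 2 of 2 against 0.410, and 1.82% had as many. The gain at Ccnd3 was not kept with lists of equal length, and that gene has a near neighbour. Cdkn1c, the gene for the cyclin-dependent kinase inhibitor p57, lies on chromosome 7 from 143458339 to 143461059. It had a new H3K4me3 peak of 0.872 kb with a fold enrichment of 8.17 beside H3K27me3 of 3.31 and 3.99 kb. Ccnd3, the cyclin D3 gene, had one of 0.771 kb with 6.28. In the same list Cdkn2b, the p15 gene, gained H3K27me3 over 0.605 kb, a call that was not kept at a matched background depth, and Mycn was the member that lost it, 1 of 4 that carried it. Of the neural stem and progenitor list, 20 of 26 genes carried H3K4me3 only in both conditions, and 1 of 3 without it, the cortical patterning gene Emx1, gained it, with a peak of 0.992 kb (random mean 0.481). Of the astrocyte and oligodendrocyte list, 1 of 9 gained H3K4me3, Mbp, which encodes myelin basic protein (random mean 0.819). Sox10 and Nkx2-2, factors of oligodendrocyte development, gained H3K27me3, 2 of 17 (random mean 0.599), by weak peaks of 1298 and 737 bp with fold enrichments of 4.14 and 3.90, and neither was kept at a matched background depth.

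Genes of crotonylation and of the chromatin machinery mostly kept their state. Of the list of crotonyl-CoA metabolism and crotonylation genes, 28 of 30 carried H3K4me3 only in both conditions, 0 of 2 gained it, and Cdyl, which encodes a crotonyl-CoA hydratase that acts as a corepressor, gained H3K27me3 over 0.896 kb, 1 of 30 (random mean 0.780). In the Polycomb and trithorax list 0 of 3 gained H3K4me3 and 2 of 41 gained H3K27me3, at Pcgf2, through a peak that reached further and was not kept at a matched background depth, and Pcgf3, over 1.22 kb (random mean 1.09). Of the housekeeping genes, 24 of 25 carried H3K4me3 only in both conditions, and 0 of 25 gained H3K27me3. Markers of other cell types were counted to look for a change in the culture. Microglia and blood cell markers gained H3K4me3 at 0 of 13 genes (random mean 1.04). Endothelial markers gained it at 1 of 10, Flt1, a VEGF receptor gene, and mural and fibroblast markers at 2 of 13, Kcnj8 and Col1a1 (random means 0.884 and 1.70). The same lists gained H3K27me3 at Tmem119 and C1qb, at Cldn5, and at Abcc9 and Dcn, which are 2 of 13, 1 of 11 and 2 of 11 genes (12.1%, 39.1% and 8.88% of random lists had as many). Over the 14 lists 30 of 402 genes gained H3K4me3 and 0 lost it, and 13 gained and 1 lost H3K27me3. At a matched background depth 28 of the 30 gains were kept, all but Lhx8 and Tbx1, and 9 of the 13. With lists of equal length 18 of the 30 and 4 of the 13 gains were kept, and above the median −log10 q 2 and 3, so that most gains named here rest on weak peaks.

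**Figure D4:**
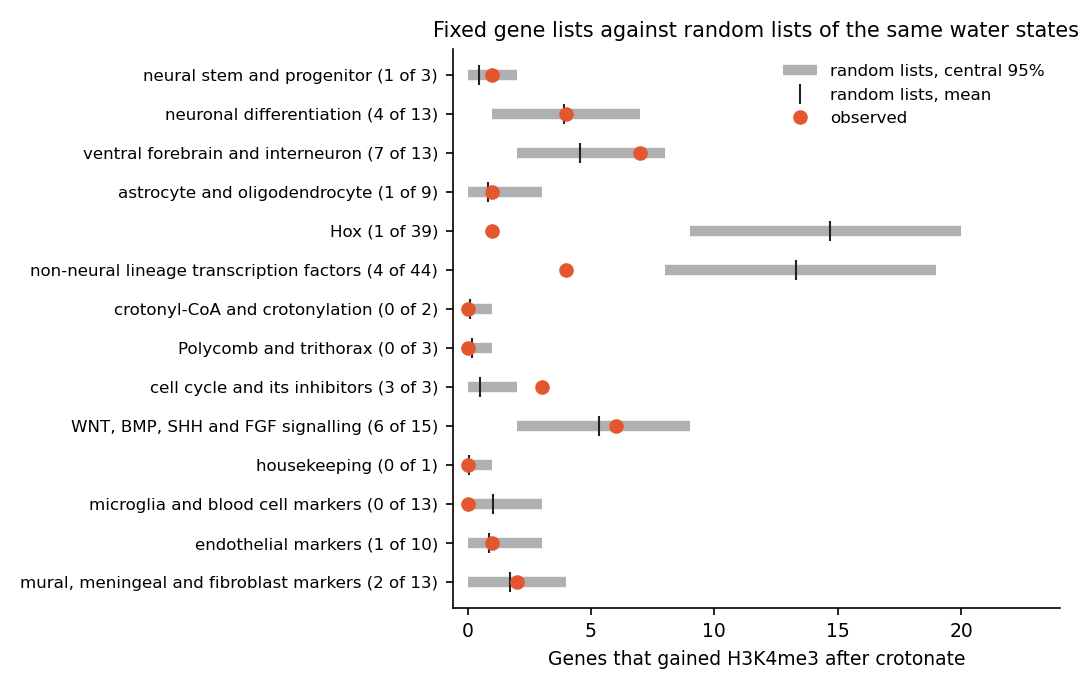
Number of genes that gained H3K4me3 after crotonate (horizontal axis) in each fixed list (vertical axis, with the number that gained it of those that lacked it); points are observed counts, ticks the mean and grey bars the central 95% of 10000 random lists matched on state in water. Hox and non-neural factor genes had fewer H3K4me3 gains than random lists, 1 and 4 against means of 14.7 and 13.3.

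Peaks of both marks were also placed along the genome. Of the H3K4me3 peaks, 81.6% lay at a gene end after water and 75.9% after crotonate, against 8.06% and 8.41% at random positions, and 47.8% (46.2 to 49.6) of those in the crotonate list only did. For H3K27me3 29.9% lay at a gene end after water and 21.1% after crotonate. Of the 10042 H3K27me3 peaks in the crotonate list only, 33.9% lay in gene bodies and 53.2% between genes, where 35.7% and 55.9% of all crotonate H3K27me3 peaks fell when placed at random. The X chromosome held 9.77% of the H3K27me3 peaks after water and 9.09% after crotonate.

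A last comparison asked whether H3K27me3 was lost more often where it overlapped H3K4me3, a test chosen after the data were seen. Of the water H3K27me3 peaks on H3K4me3, such as those at Mycn, Ndnf and Inhbb, 89 of 897 (9.92%, 8.04 to 12.1) had no counterpart after crotonate, and of all others 545 of 6746 (8.08%, 7.44 to 8.75), so that the intervals overlapped. Peaks on H3K4me3 were stronger, however, and other peaks of the same strength and length would have given 24.9 losses, so that the number lost was 3.57 times that expected. With the list split by −log10 q into 5 groups of similar size, ties kept together, 36 of 90 peaks were lost on H3K4me3 and 126 of 1429 (8.82%) elsewhere in the second-weakest group, and in the strongest group 1 of 426 and 0 of 1103. With a required reciprocal overlap of 50% the ratio turned to 0.749. With lists of equal length the plain shares turned, to 17.8% on H3K4me3 (15.4 to 20.5) and 19.7% elsewhere (18.7 to 20.6), while the matched ratio was 2.27, and at a matched background depth it was 2.85.

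**Figure D5:**
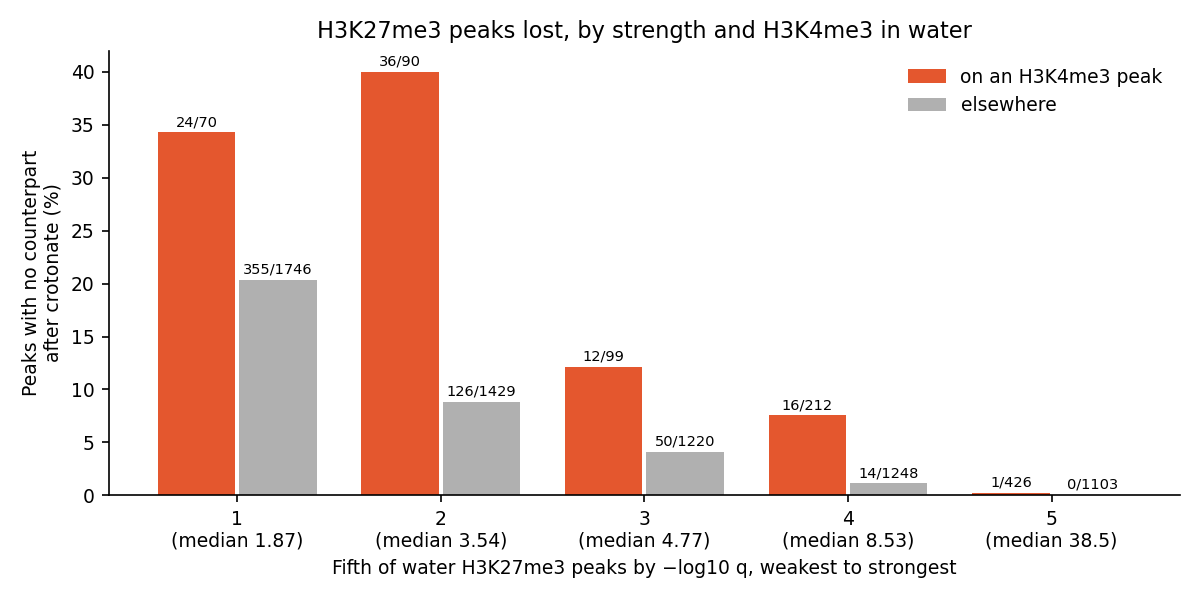
Percent of water H3K27me3 peaks with no counterpart after crotonate (vertical axis), for 5 groups of similar size of the water list from weakest to strongest −log10 q (horizontal axis), for peaks on H3K4me3 (red) and elsewhere (grey), with the number lost of all peaks above each bar. In the second-weakest group 36 of 90 were lost on H3K4me3 and 126 of 1429 elsewhere.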

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

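Gains outnumbered losses at genes for both marks under 10 of 10 alternatives that recount genes. Over 25 results and 14 alternatives, 114 values stayed within 1.5-fold or their interval, 94 moved beyond that and 1 reversed. Only ratios could be scored as reversed. The shares of H3K4me3 gains whose contrast turned above the median −log10 q therefore count among the values that moved. The settings chosen after seeing the data were the matched background depth, genes without a near neighbour, the end with H3K4me3, whole gene bodies and all values of the loss of H3K27me3 on H3K4me3. The outermost 5′ transcription start, intended as another window, was not run, because the gene table has no strand. No paired analysis was possible because each group had 1 sample. Depth limits what can be said of weak peaks, since the background was 1.80 times as deep after crotonate. The stricter, equal-length and matched settings remove peaks by construction, and the cause of the other moves was not tested.

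With peaks at or above the median −log10 q, the crotonate to water ratio of peak numbers was 1.504 for H3K4me3 and 1.82 for H3K27me3, and that of covered length 1.78 and 1.51. Under it 44 H3K4me3 and 256 H3K27me3 peaks were in water only and 3739 H3K27me3 peaks in crotonate only, and 93.3% of water H3K27me3 peaks were shared. H3K4me3 was gained by 3111 genes and lost by 38, and in the fixed lists gained by 69, while H3K27me3 was gained by 8 list genes and lost by 2. Most of the 3111 had a weaker H3K4me3 peak called in water that this threshold dropped. Both marks lay at 74 genes in water and 364 after crotonate, 78.4% of the former kept both and 17.6% lost H3K27me3. H3K4me3 was gained by 17.9% of H3K27me3-only genes and 21.7% of genes with neither mark, and lost H3K27me3 peaks on H3K4me3 were 5.18 times the number expected. With a fold enrichment of 5 or more, the ratios of peak numbers were 1.14 and 1.77, that of H3K27me3 length 1.502, and the shared water peaks 98.7% (164 H3K4me3 peaks in water only) and 89.1% (4213 H3K27me3 peaks in crotonate only). H3K4me3 was lost by 34 genes and 1 list gene, H3K27me3 was gained by 8 list genes and lost by 3, 86.3% of genes with both marks kept both and 11.8% lost H3K27me3, 6.98% of genes with neither mark gained H3K4me3, and the expected number of losses on H3K4me3 was exceeded 2.82 times.

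With lists of equal length, 97.0% of H3K4me3 and 80.6% of H3K27me3 water peaks were shared, with 398 and 1486 peaks in water only and 898 and 2776 in crotonate only. H3K4me3 was gained by 502 genes (18 in the lists) and lost by 82 (2 in the lists), and H3K27me3 gained by 311 (4) and lost by 201 (5). Of genes with both marks 82.1% kept both and 15.6% lost H3K27me3, H3K4me3 was gained by 20.4% of H3K27me3-only genes and 3.09% of genes with neither mark, and the losses on H3K4me3 were 2.27 times those expected. A reciprocal overlap of 50% left 86.4% of H3K4me3 and 43.9% of H3K27me3 water peaks shared, with 1800 and 4289 in water only, and reversed the losses on H3K4me3 to 0.749 times those expected, for which the cause was not tested. Sharing within 1 kb gave 99.5% and 95.6%, with 336 H3K27me3 peaks in water only and a ratio of 5.49. Merging within 1 kb left 2221 H3K4me3 peaks in crotonate only. Windows of 5 kb gave 21 list genes with gained H3K27me3, and windows of 1 kb gave 2 with lost H3K27me3.

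At the matched background depth the ratios of peak numbers were 1.14 and 1.47 and that of H3K27me3 length 1.46. Shared water peaks were 98.9% and 87.0%, with 147 and 997 in water only and 5860 H3K27me3 peaks in crotonate only. H3K4me3 was lost by 18 genes and H3K27me3 by 139 (3 in the lists), 87.4% of genes with both marks kept both and 12.1% lost H3K27me3, H3K4me3 was gained by 34.1% of H3K27me3-only genes and 5.00% of genes with neither mark, and losses on H3K4me3 were 2.85 times those expected. Among the 12616 genes without a near neighbour, H3K4me3 was gained by 512 and lost by 6 and H3K27me3 gained by 404 and lost by 44. Both marks lay at 497 of them in water and 885 after crotonate. These counts fall with the number of genes. Of those with neither mark, 3.67% gained H3K4me3, against 5.56% of all genes with neither mark, and the cause of this lower share was not tested. At the end with H3K4me3, H3K27me3 was gained by 254 genes (3 in the lists) and lost by 2 list genes. Over whole gene bodies H3K4me3 was lost by 7 genes, and of genes with both marks 94.3% kept both and 5.57% lost H3K27me3.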

Other observations

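Gene families defined by their symbols were examined after the data were seen, 20 in all, against random lists matched on state in water. Each family was scored for the gain and the loss of each mark, and mainly those with extreme counts are named. Among so many counts, some low percentages of random lists would arise without any cause. Potassium channel genes (Kcn) stood out for H3K27me3: 13 of the 60 that lacked it gained it, among them Kcnc2, Kcnj4, Kcnj6, Kcnk3 and Kcnj11, against a random mean of 2.24, and none of 10000 random lists had as many. At the matched background depth 12 of the 13 were kept. Receptor genes for serotonin, dopamine and adrenaline gained H3K27me3 at 4 of 10, Htr5b, Drd1, Htr1f and Htr4, against a mean of 0.417 (0.02% of random lists had as many), and gained H3K4me3 at 8 of 18, against 4.55 (4.90% had as many). All 4 and all 8 were kept at the matched depth. Zinc finger genes (Zfp) gained H3K4me3 at 13 of 76, against 5.16 (0.14% had as many), of which 10 were kept, and gained H3K27me3 at 4 of 387, against 11.2 (1.05% had as few). The same family lost H3K27me3 at 3 of 10, against 0.549 (1.26% had as many).

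Olfactory receptor genes, which are expressed mainly in sensory neurons of the nose, gained H3K4me3 at 1 of 1110, against a mean of 63.9, and H3K27me3 at 9 of 1103, against 53.3. Nkx homeobox genes gained H3K4me3 at 0 of 9, against 3.39 (1.35% of random lists had as few), and keratin genes at 1 of 51, against 4.44 (4.69%). For H3K27me3 the keratin genes lay above the mean, with 5 of 48 against 2.25 (7.15% had as many), as did Fox genes, with 3 of 21 against 0.661 (2.55%), Tbx genes, with 2 of 5 against 0.207 (1.58%), glutamate receptor genes, with 2 of 11 against 0.319 (3.8%), and Nkx genes, with 1 of 1 against 0.026 (2.60%). At the matched background depth 4 of the 5 keratin, 3 of the 3 Fox, 1 of the 2 Tbx, 1 of the 2 glutamate receptor and 0 of the 1 Nkx gains were kept. Protocadherin genes appeared to gain H3K4me3 at 24 of 58, against 4.21, but only 9 distinct peaks lay behind the 24. Of these genes 19 were protocadherin gamma genes annotated with a common end near 37841870 on chromosome 18, where 1 peak of 1.02 kb, from 37842309 to 37843326, marked them all. In a comparison added after the data were seen, random genes were also matched by 4 groups of H3K27me3 peak length. Non-neural factor genes with H3K27me3 only then gained H3K4me3 at 3 of 34, against a mean of 11.6 (0.04% had as few), and ventral forebrain genes at 7 of 12, against 4.16 (7.62% had as many). The Hox genes, with a median of 132 kb, were far longer than most of the longest group and so were not matched on length.

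Technical explanations were weighed for 3 patterns, and the tests of a deeper H3K27me3 library, at the matched background depth, on genes without a near neighbour and all tests of the third pattern were chosen after the data were seen; the treatment as a biological explanation stays open and untested, with 1 library per group. The first pattern was the larger number of H3K27me3 peaks after crotonate, 15879 against 7643. A deeper crotonate library is argued against by the estimated fragments, 0.810 times as many as after water, if the assumptions behind that estimate hold. Peak calling against a deeper background cannot be told apart from a spread of the mark: at a matched background depth the ratio fell from 2.08 to 1.47, short of both bounds set, which were 1.1 and 1.5. Part of the excess may thus come from the background, and the crotonate-only peaks, short and mostly away from gene ends, would need replicates to be read as a change.

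The second pattern was the gain of H3K4me3 at genes with H3K27me3 only in water, such as Dlx5, Fezf2 and Cdkn1c. Background depth is argued against, since at the matched depth the share of these genes that gained the mark was still 6.82 times that of genes with neither mark, and peaks of neighbouring genes are argued against by a ratio of 10.1 among genes with no near neighbour. Above the median −log10 q, however, the contrast turned, to 17.9% against 21.7%, among genes whose state in water was called anew at that threshold. What stays open is that these sites lay just under the threshold in water. The median −log10 q of the gained peaks was 8.06, at percentile 18.7 of the crotonate list, below the bound of 25 named for that explanation. That test cannot decide, since all H3K4me3 peaks in the crotonate list only had a median of 4.61, under the list's percentile 25 of 14.9. A candidate explanation is weak H3K4me3 at Polycomb genes in water that passed the threshold after crotonate. The lists cannot separate it from a new appearance of the mark. The compared genes also differ in kind, since 1103 of the 8946 genes with neither mark were olfactory receptor genes. Whether that accounts for part of the contrast was not tested.

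The third pattern was the loss of H3K27me3 where it overlapped H3K4me3, as at Mycn and Ndnf. Weak peaks alone are argued against: other peaks of the same strength and length predicted 3.57 times fewer losses, although an earlier test that it replaced, the percentile of the lost peaks, gave 28.4 and decided nothing, and a reciprocal overlap of 50% turned the ratio to 0.749. Untargeted cutting at open promoters was to be read from H3K4me3 peaks at the lost sites at percentile 75 or more of the water list. Their median was at 33.8. That test cannot decide, since sites that kept the mark lay at 17.8, so H3K4me3 was weak at sites with both marks in general. Lost sites had stronger H3K4me3 peaks than kept sites, with a median −log10 q of 25.3 against 11.5, the direction this explanation would give. It stays open. A higher local background after crotonate at those sites cannot be told apart: relative to the floor it did not rise at lost sites (median ratio 1.002) and fell at kept sites (0.787), so that the change was 1.27 times that at kept sites, between the bounds of 1.1 and 1.5.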
